A study of Mus musculus with 16 samples.

How the data were processed

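The series holds 16 mRNA libraries of C57BL/6J bone marrow-derived macrophages in a design of PTEN by fludarabine, with 4 libraries in each of 4 groups. Bone marrow was differentiated with M-CSF for 7 days, driven toward an M2-like state by 48 hours of IL-4 plus IL-13, and then given PTEN at 100 ng/mL or PBS for 24 hours, each with fludarabine (a purine nucleoside analogue used as a STAT1 inhibitor) or its solvent DMSO. The groups are named DMSO+PBS, DMSO+PTEN, Fludarabine+PBS and Fludarabine+PTEN. The sample records call the source naive macrophages, whereas the series design calls the cells M2 macrophages. The labels do not say whether libraries of one group came from separate mice or cultures, and they give no sequencing batch. No group received a heat-inactivated or other control preparation of PTEN, and one dose was used. According to the labels, mRNA was captured with poly-T beads and primed with random oligonucleotides, and a SMARTER mRNA-Seq kit is named as well. Strandedness is not stated, so sense and antisense transcripts of one locus could not be told apart.

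The authors provided 1 table with counts and FPKM for 21959 genes in all 16 libraries. Per the file headers, the deposited values are read counts (unit: counts) and FPKM (unit: fpkm). The authors' processing notes name fastp 0.22.0, HISAT2 2.1.0, HTSeq 0.9.1 and genome build mm39, without an annotation release. Counts were whole numbers. The FPKM denominators implied by 4087 genes equalled the column totals of the counts within a relative difference of 4.66e-12, so FPKM added no information on scaling and was not used for tests. Gene symbols were assigned by Ensembl identifier from an annotation of another genome build, so that no coordinates are given and some older symbols appear (Ddx58, Hist1h1c, Atp5a1). Of the 21959 identifiers, 21851 received a symbol and 108 did not.

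Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by edgeR's filterByExpr by group, which left 11680 genes. Library sizes were scaled with TMM factors, and a negative binomial model with one mean per group was fitted to all 16 libraries together. Contrasts were tested with edgeR's robust quasi-likelihood F test and Benjamini-Hochberg adjustment over all genes tested, at a false discovery rate of 0.05 without a minimum fold change. The 5 contrasts were PTEN without fludarabine, PTEN with fludarabine, the difference between these effects (the interaction), fludarabine without PTEN and fludarabine with PTEN. CPM values are counts scaled by TMM-corrected library size with edgeR's cpm function. The effects of PTEN without fludarabine and of fludarabine without PTEN share the DMSO+PBS libraries, and were therefore not compared with each other. The PTEN effects with and without fludarabine use disjoint libraries, and their relation was summarised by a slope through the origin. For the slope, genes were chosen at a false discovery rate of 0.05 in one pair each of the DMSO+PTEN and DMSO+PBS libraries and their effect was read in the remaining DMSO libraries, over 6 halvings.

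A set of 40 gene lists for macrophage activation, signalling, cell cycle, metabolism, stress, RNA quality and other cell types was written, and 995 of 1001 list symbols were found in the table. The 35 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. Several lists share members, for instance Icam1 in the NF-kB and STAT1 lists and Bst2 in the interferon and dendritic cell lists. Genes named in the text follow a rule. Per contrast these are the 12 largest increases and 12 largest decreases (6 each for fludarabine with PTEN) among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups compared, up to 4 members per list with the smallest adjusted p, and 24 genes named whatever their result. The overlap criterion did not apply to the interaction. Contrasts, tests, lists, the naming rule and the alternatives were chosen before the data were examined, except where stated. Reads of near-identical genes (histone copies, Ifit3 and Ifit3b, Bcl2a1a, Bcl2a1b and Bcl2a1d, Tgtp1 and Tgtp2) may be assigned to one another or dropped.

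The libraries held 15.2 to 20.1 M counted reads and 13399 to 14002 genes with a count. Mean TMM factors were 1.09 for DMSO+PBS, 0.809 for DMSO+PTEN, 1.10 for Fludarabine+PBS and 1.03 for Fludarabine+PTEN. The biological coefficient of variation from edgeR within a group was 3.63%, 4.86%, 3.20% and 4.45% in the same order, and may hold technical spread. Replicates were also compared by chi-square per gene, lower when closer. In DMSO+PBS it was 1.57 for replicates 1 and 3, 2.05 for 2 and 4 and 3.59 to 3.96 for other pairs. In Fludarabine+PTEN it was 1.95, 3.17 and 4.20 to 5.89. DMSO+PTEN and Fludarabine+PBS did not split this way (6.43 and 3.73 for replicates 2 and 4). The labels do not say whether closer libraries share a culture. Folds against a group with 1 to 3 counts in all its libraries together are given as count ratios with a 95% counting interval, which covers counting error only. An interaction in such a gene is a fitted value whose size is not reliable. The steps were tested on simulated data with the real means, library sizes and dispersions and 50 changed genes per fold. At 2-fold, 98% were recovered for PTEN without fludarabine, 90% for PTEN with fludarabine, 82% for the interaction, 92% for fludarabine without PTEN and 82% for fludarabine with PTEN. At 1.2-fold, recovery was 54%, 62%, 38%, 60% and 48%. False calls numbered 13 of 179 calls, 13 of 182, 7 of 155, 5 of 177 and 11 of 166 in the same order. A simulated slope of 0.3 was recovered as 0.294, shares of 0.2 and 0.4 as 0.199 and 0.400, and of 35 simulated lists camera called the 1 that had been changed. In the simulated folds most genes were unchanged (11464 of 11664 for PTEN without fludarabine), unlike in the data, and genes were drawn independently. The recovery and false-call rates therefore do not cover a broad shift in composition. The simulated list result does not cover correlated genes.

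Alternatives were RLE factors, library size without a composition factor, no filter on low counts, DESeq2 1.42.0, a fit of the compared groups only, replicate number as a block, a minimum of 2-fold, an estimated correlation for lists, and leaving out each library in turn. Shares of the PTEN response per list, in CPM and on a log2 scale with prior counts of 2 and 20, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.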

Results

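The 16 libraries separated by PTEN and by fludarabine. On the first principal component of log2 CPM, with 81.6% of the variance, the 4 DMSO+PTEN libraries lay between 97.2 and 106, the 4 Fludarabine+PTEN libraries between -4.51 and 2.45, and the 8 libraries without PTEN between -51.9 and -48.0. The second component, with 9.12%, separated fludarabine from DMSO in cells with PTEN (25.1 to 31.2 against -10.0 to -7.87) and without it (7.51 to 12.2 against -29.7 to -26.3). All p-values below measure only the spread between these libraries, which may be technical, because the labels do not say whether the 4 libraries of a group are separate cultures or mice. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those for gene lists are from camera.

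The added PTEN preparation, without fludarabine, raised interferon-stimulated, STAT1-target, NF-kB-target, class I antigen-presentation and late lipopolysaccharide-response transcripts together in M2-like macrophages. Stat1 rose from 24.4 to 401 CPM (log2 fold change 4.04, SE 0.05, edgeR adjusted p = 3.64e-33). Jak2 went from 86.6 to 1013 CPM, Irf1 from 43.6 to 797 CPM, Gbp2 from 24.7 to 4654 CPM and Tnf from 7.77 to 2219 CPM. Transcripts that were nearly absent without PTEN became abundant, among them Cxcl10 (0.234 to 1898 CPM), Ptgs2 (0.871 to 2005 CPM), Cxcl2 (0.437 to 1253 CPM), and Il1b (0.306 to 713 CPM). The same held for Ifi205 (0.237 to 673 CPM), Iigp1 (0.0976 to 390 CPM), Nos2 (0.0554 to 351 CPM), Cd69 (0.0675 to 329 CPM) and Cxcl9 (0.0811 to 87.3 CPM). Il6 went from 1 count in the 4 DMSO+PBS libraries together to 633 CPM, a ratio of 45887 (95% counting interval 8235 to 1812490). The ratios of Cxcl3, Il12a and Il12b, with 1 to 3 counts without PTEN, were 5526 (1890 to 26798), 4983 (894 to 196860) and 2968 (821 to 24516). In each of these genes all 4 DMSO+PTEN libraries lay above all 4 DMSO+PBS libraries.

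All 42 interferon-stimulated genes of the list were higher with PTEN (median log2 fold change 4.80, camera adjusted p = 9.37e-122), including, by smallest adjusted p, Ifi44 (8.02), Trim30d (4.71), Slfn5 (4.70) and Ddx58 (4.64). Among interferon-gamma and STAT1 targets 34 of 35 were higher and 1 lower (median 4.65, camera adjusted p = 5.21e-57), including Icam1 (6.13), Igtp (5.25), Irgm1 (4.67) and Gbp9 (4.14). All 32 NF-kB targets rose (median 4.71, camera adjusted p = 4.08e-44), including Traf1 (4.98), Nfkb1 (2.65) and Ikbke (2.08). All 27 M1 markers rose (median 8.13, camera adjusted p = 3.06e-27), among them Cd86 (5.10), Il15 (4.53), Il18 (3.80) and Fcgr1 (2.68). The median was 8.03 when members with at most 3 counts in one group were set to 3 counts there. Late lipopolysaccharide-response genes were higher in 28 of 29 (median 4.33, camera adjusted p = 1.27e-21), with Malt1 (3.33), Mefv (3.23) and Ptges (2.73) ahead by adjusted p and Fpr1 at a ratio of 2695 (483 to 106489) from 1 count. Chemokines were higher in 22 of 24 and lower in 1 (median 4.92, camera adjusted p = 2.06e-13), including Ccl5 (10.36), Ccl12 (6.93), Ccl9 (2.03) and Ccl8 (1.86). All 23 class I antigen-presentation genes rose (median 2.22, camera adjusted p = 1.24e-20), including H2-T24 (2.97), Psme2 (2.77), H2-T22 (2.48) and Tap1 (4.22). These 7 list results kept an adjusted p between 0.00203 and 0.0169 with an estimated correlation.

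JAK-STAT components were higher in 19 and lower in 5 of 28 (median 0.97, camera adjusted p = 2.18e-07, adjusted p = 0.0567 with an estimated correlation), with Stat2 at 3.61 and Ptpn6 at 2.07. Scaled by library size alone, 17 were higher and 10 lower (median 0.54). Apoptosis regulators were higher in 20 and lower in 5 of 29 (median 1.19, camera adjusted p = 5.61e-08, adjusted p = 0.0408 with an estimated correlation), including Cflar (3.63), Casp4 (3.55), Casp7 (2.53) and Casp1 (2.12), with 18 higher and 8 lower (median 0.75) under library size alone. NRF2 targets were higher in 13 and lower in 3 of 18 (median 0.73, camera adjusted p = 0.00555, adjusted p = 0.261 with an estimated correlation), including Txnrd1 (1.57), Prdx1 (1.48), Hmox1 (1.03) and Srxn1 (0.99), with 9 higher and 6 lower (median 0.29) under library size alone. Class II antigen-presentation genes were higher in 8 and lower in 2 of 11 (median 0.44, camera adjusted p = 0.513), but higher in 3 and lower in 5 under library size alone. H2-DMb1 (0.69), H2-Ab1 (0.63) and Cd74 (0.44) rose while their regulator Ciita fell (-0.73).

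**Figure D1:**
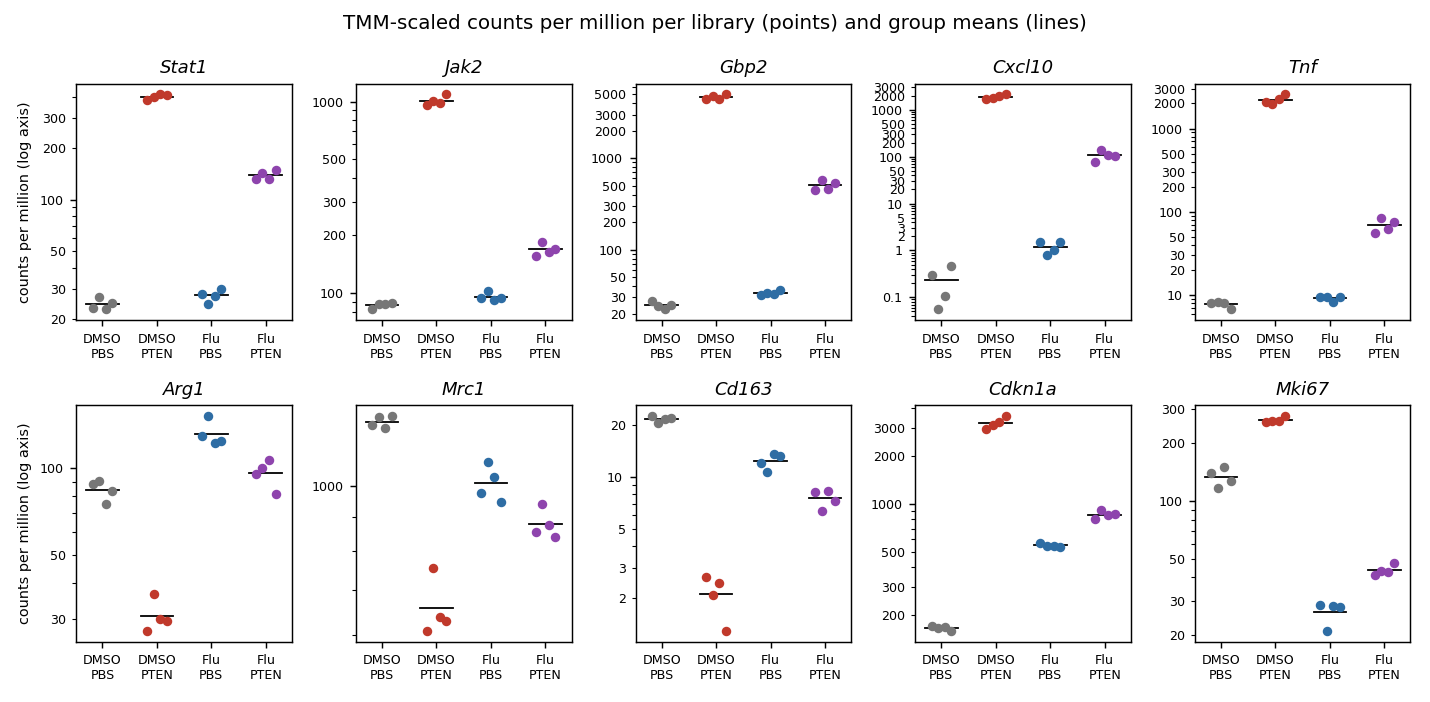
CPM of 10 genes in the 16 libraries, with 1 point per library and a line at each group mean. Stat1, Jak2, Gbp2, Cxcl10 and Tnf rose with PTEN in both backgrounds, to lower values with fludarabine.

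Markers of alternative activation went both ways with PTEN. Of 30 M2 markers 11 were higher and 16 lower, with a median of -0.22 and a mean of 0.30 (camera direction down, adjusted p = 0.745; 10 higher, 20 lower and median -0.66 under library size alone). Arg1 fell from 84.4 to 30.9 CPM (-1.44, SE 0.12, edgeR adjusted p = 4.11e-08), Mrc1 from 1249 to 658 CPM (-0.92, adjusted p = 1.76e-11) and Cd163 from 21.5 to 2.12 CPM (-3.33, adjusted p = 5.55e-23), each with 4 of 4 libraries below all controls. Matk (-2.26), Clec10a (-2.12) and Ptgs1 (-2.06) fell too. Retnla (-0.01, adjusted p = 0.929), Chil3 (0.00, adjusted p = 0.99) and Plxdc2 (0.03, adjusted p = 0.763) did not change. Under library size alone they fell (-0.45, -0.43 and -0.41, with edgeR adjusted p = 0.00141, 0.0221 and 1.64e-05). Il10 (0.38, adjusted p = 0.175) was not different, and passed the threshold without DMSO+PTEN replicate 1 (adjusted p = 0.0247). Endogenous Pten transcript fell (-0.45, SE 0.04, edgeR adjusted p = 2.79e-11), with all 4 DMSO+PTEN libraries below the controls.

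Replication and mitosis transcripts mostly fell with PTEN. The largest decreases were Cxcr4 (66.4 to 1.56 CPM, -5.41), Lpin1 (-5.22), Thbd (-5.11), Fam214a (-4.89), Galnt9 (-4.85), Ier5l (-4.83), Cnr2 (-4.78), E2f2 (-4.62), Rnf150 (-4.59), Rasgrp3 (-4.53), Smpd3 (-4.51) and Bmf (-4.51). Replication and G1/S genes were lower in 31 and higher in 5 of 39 (mean -0.85, camera adjusted p = 0.00197, adjusted p = 0.252 with an estimated correlation). Mcm2 (-2.10), Cdt1 (-1.92), Mcm7 (-1.65) and Pcna (-0.67) were among them. Mitosis genes were lower in 37 and higher in 2 of 40 (median -1.16, camera adjusted p = 0.00117, adjusted p = 0.57 with an estimated correlation). Kif23 (-2.90), Cenpa (-2.31) and Anln (-1.97) were lower, but Tpx2 (1.59) and Mki67 (0.98, 134 to 263 CPM, adjusted p = 2.94e-08) higher. Histone genes were lower in 10 of 13 (median -1.20, camera adjusted p = 0.215; 0.0385 without the filter on low counts), among them Hist1h1c (-1.94), Hist1h3d (-1.88), Hist1h2bg (-0.98) and Hist1h2bc (-0.47). The p53 targets went both ways, with 14 higher and 13 lower of 33 (median 0.12, camera adjusted p = 0.757; 11 higher, 19 lower and median -0.32 under library size alone). Cdkn1a (166 to 3240 CPM, 4.29), Fas (3.80), Mdm2 (0.84) and the nucleoside kinase Dck (2.28) rose, whereas Trp53inp1 (-2.41) and Sesn1 (-2.35) fell.

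PI3K-AKT-FOXO genes were higher in 14 and lower in 20 of 36 (median -0.23, camera adjusted p = 0.104), with Foxo3 (-2.66) and Inpp5d (-1.94) down and Pik3cd (1.55) up. With library size as the only scaling, 9 were higher and 26 lower (median -0.66, camera adjusted p = 0.0349). Cholesterol synthesis genes were higher in 18 and lower in 4 of 24 (median 0.47, camera adjusted p = 0.151), including Hmgcr (1.10), Ldlr (1.02) and Cyp51 (0.86) against Dhcr7 (-1.90). With library size as the only scaling, 10 were higher and 7 lower (median 0.04), and without the filter on low counts the list was called (camera adjusted p = 0.00083). Fatty acid synthesis genes were higher in 6 and lower in 11 of 18 (median -0.29, adjusted p = 0.287; -0.73 under library size alone), with Acsl1 (4.19) up and Fads1 (-1.95) and Acsl3 (-1.65) down. LXR targets were higher in 3 and lower in 7 of 12 (median -0.24, adjusted p = 0.214; -0.68 under library size alone), with Arl4c (-1.63) and Plin2 (-1.12) down and Nr1h3 (1.36) up. Glycolysis genes were higher in 10 and lower in 6 of 18 (median 0.28, adjusted p = 0.365; 6 higher, 8 lower and median -0.16 under library size alone), including Pfkfb3 (1.84) and Slc2a1 (1.03). Hypoxia-response genes were higher in 6 and lower in 12 of 18 (median -0.59, adjusted p = 0.215; -1.02 under library size alone), with P4ha1 (1.23) up and Mxi1 (-2.17) and Bnip3l (-1.18) down. Lysosome and autophagy genes were higher in 12 and lower in 19 of 33 (median -0.20, adjusted p = 0.424; -0.64 under library size alone), with Sqstm1 (1.81) up and Sgsh (-2.88) and Tfeb (-1.47) down. Stress-response genes of the integrated and unfolded-protein pathways were higher in 14 and lower in 7 of 26 (median 0.10, adjusted p = 0.424; 6 higher, 15 lower and median -0.33 under library size alone), including Mthfd2 (1.99) and Herpud1 (1.05). Phagocytic receptors were higher in 12 and lower in 13 of 27, with a median of -0.06, a mean of 0.68 and a camera direction of up (adjusted p = 0.513; 10 higher, 15 lower and median -0.49 under library size alone), as Olr1 (4.35), Axl (2.79) and Msr1 (2.23) rose.

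Immediate-early genes were higher in 15 and lower in 5 of 20 (median 0.86, camera adjusted p = 0.0775; 0.0118 without the filter on low counts, median 0.43 under library size alone), with Klf6 (1.70) and Junb (1.45) up and Jun (-1.95) down. The list passed without DMSO+PTEN replicate 2 (0.0318) or Fludarabine+PTEN replicate 2 (0.0466). Oxidative phosphorylation genes were higher in 17 and lower in 2 of 36 (median 0.12, adjusted p = 0.838; 0 higher, 31 lower and median -0.32 under library size alone), with Uqcrfs1 at 0.45. Ribosomal protein genes were higher in 19 and lower in 2 of 42 (median 0.06, adjusted p = 0.948; 0 higher, 39 lower and median -0.37 under library size alone), with Rps24 at 0.34. Mitochondrially encoded mRNAs were higher in 6 of 11 (median 0.17, adjusted p = 0.843; 0 higher, 9 lower and median -0.26 under library size alone), with mt-Co1 at 0.29. Macrophage identity markers were higher in 12 and lower in 6 of 20 (median 0.25, adjusted p = 0.287; 8 higher, 12 lower and median -0.19 under library size alone), with Maf (1.96) and Spi1 (1.25) up and Cebpa (-2.28) down. Of 8 expressed dendritic cell markers 5 rose and 1 fell (median 1.28, camera adjusted p = 0.0066, adjusted p = 0.234 with an estimated correlation), with Fscn1 (7.12) and the interferon-stimulated Bst2 (2.84) up and Batf3 (-2.28) down. Their median was 0.84 under library size alone.

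Markers of other cell types were expressed in part. Of 9 expressed monocyte markers 5 rose and 2 fell (median 1.88, camera adjusted p = 0.424), with Vcan at 7.10. Of 6 neutrophil markers 3 rose and 2 fell (median 1.02, adjusted p = 0.296; 0.59 under library size alone), with Lcn2 at 7.38. Of 8 osteoclast markers 3 rose and 5 fell (median -0.53, adjusted p = 0.215; -0.96 under library size alone), with Itgb3 at -2.75. Of 13 fibroblast markers 4 rose and 1 fell (median 0.32, adjusted p = 0.745; 3 higher, 4 lower and median -0.12 under library size alone), with Pdgfrb at 5.09. Lists too small for camera were mast cell (Hdc 8.92 and Il4 -1.54; median of 4 genes 0.36), B cell (Cd22 -1.09, the only gene) and T and NK cell markers (Lck 3.49 and Cd247 4.56; 2 of 3 higher). They further included erythroid and megakaryocyte (Pf4 1.97 and Car2 2.20; 2 of 3 higher) and endothelial markers (Kdr 5.62, Eng 1.43, Vwf -0.93 and Pecam1 -0.82; median 0.31).

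PTEN without fludarabine changed 9245 of 11680 genes, 4253 higher and 4992 lower, of which 3350 changed at least 2-fold (1521 higher, 1829 lower). Camera called 13 of 35 lists, 8 of them with an estimated correlation as well. Adjusted over the list alone, counts per list were the same except for histone genes (0 higher, 11 lower), oxidative phosphorylation (16 higher), ribosomal proteins (15 higher) and fibroblast markers (0 lower). The split depended on scaling, because the DMSO+PTEN libraries had a mean TMM factor of 0.809. Under library size alone the median gene shifted by -0.43 and the counts became 2258 higher and 8002 lower, so that directions of small changes are uncertain.

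Fludarabine did not abolish the response to PTEN, and interferon-stimulated genes were prominent among the largest increases. The largest increases with PTEN in fludarabine-treated cells were Cxcl10 (to 108 CPM, 6.45), Iigp1 (6.15), Ifit3b (5.97), Cd69 (5.81), Ifit1 (11.1 to 622 CPM, 5.81), Gbp5 (5.80), Ifit2 (26.1 to 1412 CPM, 5.75), Slfn1 (5.67), Ifit3 (5.63), Rsad2 (5.62), Ifi208 (5.55) and Ifit1bl1 (5.54). Stat1 rose from 27.5 to 139 CPM (2.34, SE 0.05, edgeR adjusted p = 4.72e-26), Irf1 by 1.99, Gbp2 by 3.92, Cd86 by 1.83 and Jak2 by 0.82 (adjusted p = 1.95e-15). All 4 treated libraries lay above all 4 controls in each. Tnf (9.20 to 70.0 CPM, 2.92, adjusted p = 3.58e-09), Nos2 (4.01), Il1b (3.85) and Il6 (4.76, adjusted p = 0.00056) rose as well. Nos2 reached 10.3 CPM, Il6 4.86 CPM and Cxcl9 4.52 CPM (6.04). The group means of Il12a and Il12b stayed below 1 CPM, with ratios of 31.2 (5.14 to 1276) and 37.0 (9.82 to 312).

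All 42 interferon-stimulated genes were again higher (median 2.94, adjusted p = 3.32e-06 with an estimated correlation in camera), including, by smallest adjusted p, Ifi44 (4.56), Slfn5 (2.90), Ddx58 (2.89) and Trim30d (2.88). Interferon-gamma and STAT1 targets were higher in 32 and lower in 1 of 35 (median 2.34, camera adjusted p = 3.32e-114), including Igtp (2.92), Irgm1 (2.79) and Gbp9 (2.38). NF-kB targets were higher in 31 of 32 (median 1.43, camera adjusted p = 1.82e-37), with Icam1 (1.74), Nfkbie (1.73), Tnip3 (0.98) and Ikbke (0.91). M1 markers were higher in 24 of 27 (median 2.92, camera adjusted p = 5.84e-31), with Fcgr1 (1.68) and Il15 (1.66). Class I antigen-presentation genes were higher in 22 of 23 (median 0.93, camera adjusted p = 9.28e-25), with Nlrc5 (2.16), Tap1 (1.94) and H2-T24 (1.72). Late lipopolysaccharide-response genes were higher in 22 of 29 (median 1.09, camera adjusted p = 4.37e-15), with Acod1 (5.14), Clec4e (3.90), Tlr2 (2.15) and Malt1 (0.49). Chemokines were higher in 18 of 24 (median 0.99, camera adjusted p = 1.08e-10), with Ccl5 (4.40), Ccl12 (3.83) and Ccl9 (0.46). These lists kept an adjusted p of at most 0.0339 with an estimated correlation. With members of at most 3 counts in one group set to 3 counts there, and those at or below 3 in both left out, the medians were 2.76 for M1 markers, 1.47 for NF-kB targets and 1.41 for late lipopolysaccharide-response genes.

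JAK-STAT components (16 higher, 3 lower of 28; median 0.16, camera adjusted p = 5.18e-06, adjusted p = 0.11 with an estimated correlation), apoptosis regulators (19 higher, 4 lower of 29; median 0.28, camera adjusted p = 1.54e-05, adjusted p = 0.109 with an estimated correlation) and NRF2 targets (14 of 18 higher; median 0.39, camera adjusted p = 0.00174, adjusted p = 0.238 with an estimated correlation) were higher in part. With library size alone, JAK-STAT components were higher in 12 and lower in 9 (median 0.05), and apoptosis regulators higher in 15 and lower in 4 (0.18). Stat2 (2.49), Il13ra1 (1.55), Casp4 (1.75), Casp1 (0.82), Prdx1 (0.58) and Txnrd1 (0.52) were among their members. M2 markers were higher in 12 and lower in 7 (median 0.03; 6 higher, 11 lower and median -0.08 under library size alone), with Flt1 (1.35) up and Matk (-0.32) down. Replication genes (2 higher, 8 lower; median -0.12, camera adjusted p = 0.261) and mitosis genes (2 higher, 5 lower; median -0.15, camera adjusted p = 0.189; 0.0471 without the filter on low counts) changed in few members, of which Mki67 (0.72) and Tpx2 (0.62) rose and Cenpa (-0.95) fell. With library size alone 16 replication genes (median -0.22) and 13 mitosis genes (-0.26) were lower.

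Decreases with PTEN in fludarabine-treated cells were small. The largest were Slc26a11 (-1.58), Hpgd (-1.31), Arhgap19 (-1.26), Thbd (-1.23), Gadd45a (-1.22), Engase (-1.14), Scn3a (-1.09), Rnf150 (-1.07), Slco2b1 (-1.06), Cnrip1 (-1.04), Cxcr4 (-1.03) and Fam214a (-0.99). Arg1 (-0.45, edgeR adjusted p = 0.00204), Mrc1 (-0.20, adjusted p = 0.0086) and Cd163 (-0.72, adjusted p = 2.94e-07) fell, and Retnla (-0.06), Chil3 (-0.21, adjusted p = 0.368) and Plxdc2 (-0.03) did not change. Chil3 passed the threshold with replicate number as a block (adjusted p = 0.0249). Pten transcript was not different (-0.08, adjusted p = 0.155), but passed without Fludarabine+PTEN replicate 3 (adjusted p = 0.0181) and under library size alone (adjusted p = 0.000706). Il10 rose from 0.439 to 1.79 CPM (2.02, adjusted p = 8.04e-07), Cdkn1a by 0.64 and Dck by 1.92, and Mdm2 (0.13, adjusted p = 0.00141) lost its call under library size alone (adjusted p = 0.537).

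PTEN with fludarabine changed 4076 genes, 2366 higher and 1710 lower, of which 489 changed at least 2-fold (450 higher, 39 lower). Camera called 10 of 35 lists, 7 of them with an estimated correlation as well. Adjusted over the list alone, the counts given above were the same except for interferon-gamma and STAT1 targets (2 lower), JAK-STAT components (5 lower), late lipopolysaccharide-response genes (23 higher), and chemokines (19 higher). Other exceptions were M2 markers (9 lower), replication genes (7 lower) and mitosis genes (3 lower). Under library size alone the median gene shifted by -0.10, with 1465 genes higher and 4021 lower, and 3174 of the 4076 calls were kept.

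**Figure D2:**
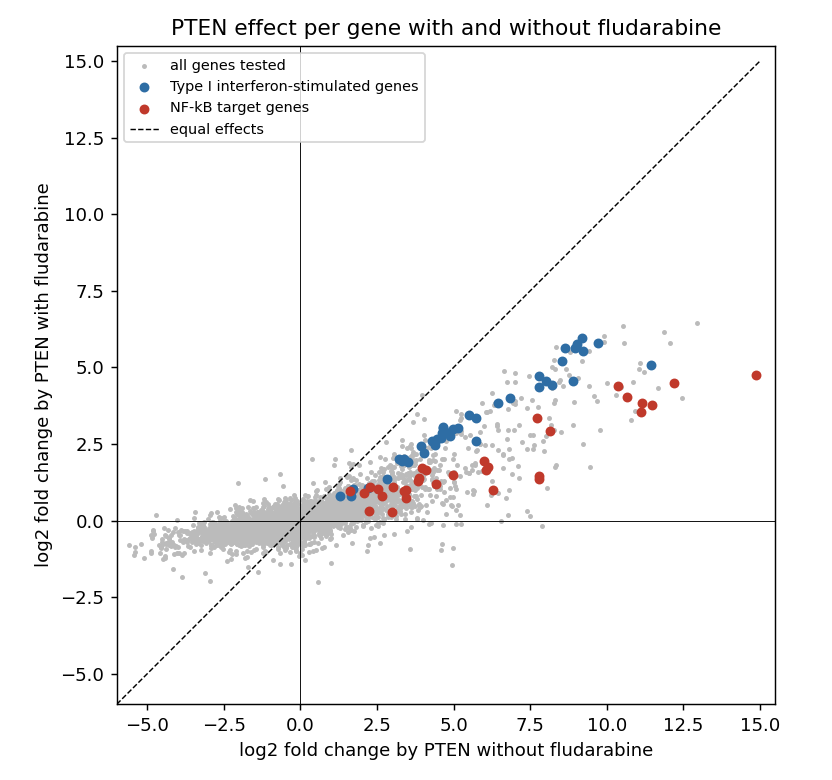
Log2 fold change with PTEN in cells with fludarabine against that in cells without it, for all genes tested (grey), interferon-stimulated genes (blue) and NF-kB targets (red), with a dashed line at equal effects. Interferon-stimulated genes lay nearer to the dashed line than NF-kB targets.

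Genes that responded to PTEN mostly moved in the same direction with fludarabine, at a lower amplitude, and many of them were no longer called. Across genes, the log2 effects correlated at r = 0.824, where genes are not independent replicates. The effect with fludarabine had a slope of 0.306 on the effect without it (range 0.302 to 0.310 over 6 halvings of the DMSO libraries), 0.369 for increases such as Stat1 and Cxcl10 and 0.151 for decreases such as Cxcr4 and Lpin1. Of the 9245 genes changed without fludarabine, 7792 moved in the same direction with it, 9077 had a smaller effect and 7470 a smaller effect with an interaction past the threshold. Unlike the slope, these counts use genes chosen in the same DMSO libraries, which favours a smaller effect with fludarabine. In the halvings, effects of genes chosen in one part of the DMSO libraries had a mean slope of 0.968 in the remaining part. Genes higher in both settings numbered 2145, against 861.5 for independent sets, and genes lower in both 1573, against 730.8. Another 143 genes were called in both settings with opposite directions.

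The interaction was negative for the inflammatory genes that PTEN raised and positive for many that it lowered. Interaction values were -1.70 for Stat1 (SE 0.08, edgeR adjusted p = 1.27e-18), -2.73 for Jak2 (adjusted p = 7.72e-25), -2.20 for Irf1, -3.64 for Gbp2, -3.27 for Cd86, -5.23 for Tnf (adjusted p = 4.05e-10) and -6.49 for Cxcl10 (adjusted p = 5.3e-05). Strongly negative values were found for Nos2 (-8.44), Cxcl2 (-7.72), Ptgs2 (-7.58), Il1b (-7.31), Shisa3 (-6.99), Col27a1 (-6.72) and Cxcl1 (-6.63). The size for Nos2 is uncertain, because it had 1 count in each DMSO+PBS library. Il6 (adjusted p = 0.0138), Gfi1 (adjusted p = 0.00111), Cxcl3 (adjusted p = 0.0214), Fpr1 (adjusted p = 3.79e-08) and Adamts4 (adjusted p = 0.0314) were negative too, but had 1 to 3 counts in DMSO+PBS, so their fitted sizes are not reliable. In Gfi1 the PTEN ratio was 881 (243 to 7281) without and 4.04 (0.770 to 39.9) with fludarabine. Cxcl3 was not called without Fludarabine+PBS replicate 2 (adjusted p = 0.103). Adamts4 was not called without DMSO+PBS replicate 2 (0.051) or 4 (0.0504), without Fludarabine+PBS replicate 1 (0.187), 3 (0.0586) or 4 (0.0589), or without the filter on low counts (0.0536). Il12b (adjusted p = 0.245, with 2 counts in each group without PTEN) and Cxcl9 (-3.89, adjusted p = 0.149) were not called, but DESeq2 called them (2.51e-05 and 7.28e-05), and Il12b passed without DMSO+PTEN replicate 4 (0.0457) and with replicate number as a block (0.0382).

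The most positive interactions were Angptl4 (4.80), Ier5l (4.49), Lpin1 (4.47), Cxcr4 (4.38), Cnr2 (4.35), Galnt9 (4.27), Klhl3 (4.22), Lpar5 (3.94), Rasgrp3 (3.93), Fam214a (3.90), Thbd (3.88) and Lbh (3.83). Arg1 (0.99, edgeR adjusted p = 5.46e-05), Mrc1 (0.72), Cd163 (2.61), Il10 (1.64, adjusted p = 0.000578) and Pten (0.37, adjusted p = 2.25e-06) were positive too. Retnla (-0.05, adjusted p = 0.794), Chil3 (-0.21, adjusted p = 0.449) and Plxdc2 (-0.06, adjusted p = 0.656) showed no interaction. Plxdc2 passed under library size alone (0.27, edgeR adjusted p = 0.0129). Cdkn1a (-3.64) and Mdm2 (-0.71) were negative. Fludarabine alone raised Cdkn1a and Mdm2 and lowered Il10, so these interactions include a shifted starting level. In PTEN-treated cells, Mdm2 was higher with fludarabine than without it, and Il10 was not different. Dck (-0.36, adjusted p = 6.94e-07) lost its call under library size alone (adjusted p = 0.614). Mki67 (-0.26, adjusted p = 0.0928) passed with RLE factors (0.0428), without DMSO+PBS replicate 3 (0.0196), without Fludarabine+PBS replicate 2 (0.00316) and in DESeq2 (0.00649).

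Among lists, interferon-stimulated genes (42 of 42 lower; median -1.97, camera adjusted p = 1.66e-44), NF-kB targets (32 of 32 lower; -3.35, 2.93e-39), and interferon-gamma and STAT1 targets (33 lower, 1 higher; -2.32, 1.96e-27) had negative interactions. Class I antigen presentation (21 of 23 lower; -1.25, 8.19e-15), late lipopolysaccharide-response genes (25 lower, 1 higher; -2.85, 5.03e-15) and chemokines (20 lower, 1 higher; -3.50, 1.08e-09) did so too. Members with the smallest adjusted p included Slfn5 (-1.81), Icam1 (-4.39), Nfkb1 (-1.87), Igtp (-2.33), Tap1 (-2.27), Malt1 (-2.85) and Ccl9 (-1.58). The 6 lists kept an adjusted p of at most 0.0372 with an estimated correlation. M1 markers (23 of 27 lower; median -4.97, camera adjusted p = 6.06e-15, adjusted p = 0.0505 with an estimated correlation), JAK-STAT components (19 lower, 5 higher; -0.70, 3.66e-06, adjusted p = 0.078 with an estimated correlation) and apoptosis regulators (20 lower, 5 higher; -0.71, 4.35e-07, adjusted p = 0.05 with an estimated correlation) were negative as well. Il18 (-3.09), Il15 (-2.88), Tyk2 (-1.35), Stat5a (-1.62), Cflar (-2.60) and Casp7 (-1.94) belonged to these 3 lists. Scaled by library size alone, the medians were -0.37 for JAK-STAT components (17 lower, 8 higher) and -0.38 for apoptosis regulators (18 lower, 8 higher). Dendritic cell markers (5 lower, 1 higher of 8; median -1.08, camera adjusted p = 0.0145, adjusted p = 0.238 with an estimated correlation) and NRF2 targets (10 lower, 3 higher; median -0.33, camera adjusted p = 0.0195, adjusted p = 0.307 with an estimated correlation) followed, the latter with 8 higher, 9 lower, a median of 0.00 and adjusted p = 0.0833 under library size alone. Replication genes (30 higher, 4 lower; median 0.81, camera adjusted p = 0.00157, adjusted p = 0.208 with an estimated correlation) and mitosis genes (32 higher, 1 lower; 1.01, 0.00356, adjusted p = 0.584 with an estimated correlation) were positive, with Mcm2 (1.91), Cdt1 (1.55) and Kif23 (2.53), against Tpx2 (-0.97). The mitosis call was lost under library size alone (adjusted p = 0.0572). Fludarabine without PTEN already lowered nearly all members of the replication and mitosis lists, as given below. Their positive interactions therefore cannot be told apart from a lowered starting level. M2 markers had a median of 0.28 and a mean of -0.13 (camera direction up, adjusted p = 0.568; median 0.61 under library size alone).

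An interaction was found for 7671 genes, 4217 positive and 3454 negative, of which 2475 were at least 2-fold (1377 positive, 1098 negative). Camera called 13 of 35 lists, 6 of them with an estimated correlation as well, and adjusted over the list alone the counts above were the same except for late lipopolysaccharide-response genes (26 lower). Under library size alone the median gene shifted by 0.33, with 7139 genes positive and 1935 negative. An interaction on the log2 scale does not by itself separate a lost pathway from a weaker one, or from a starting level shifted by fludarabine.

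**Figure D3:**
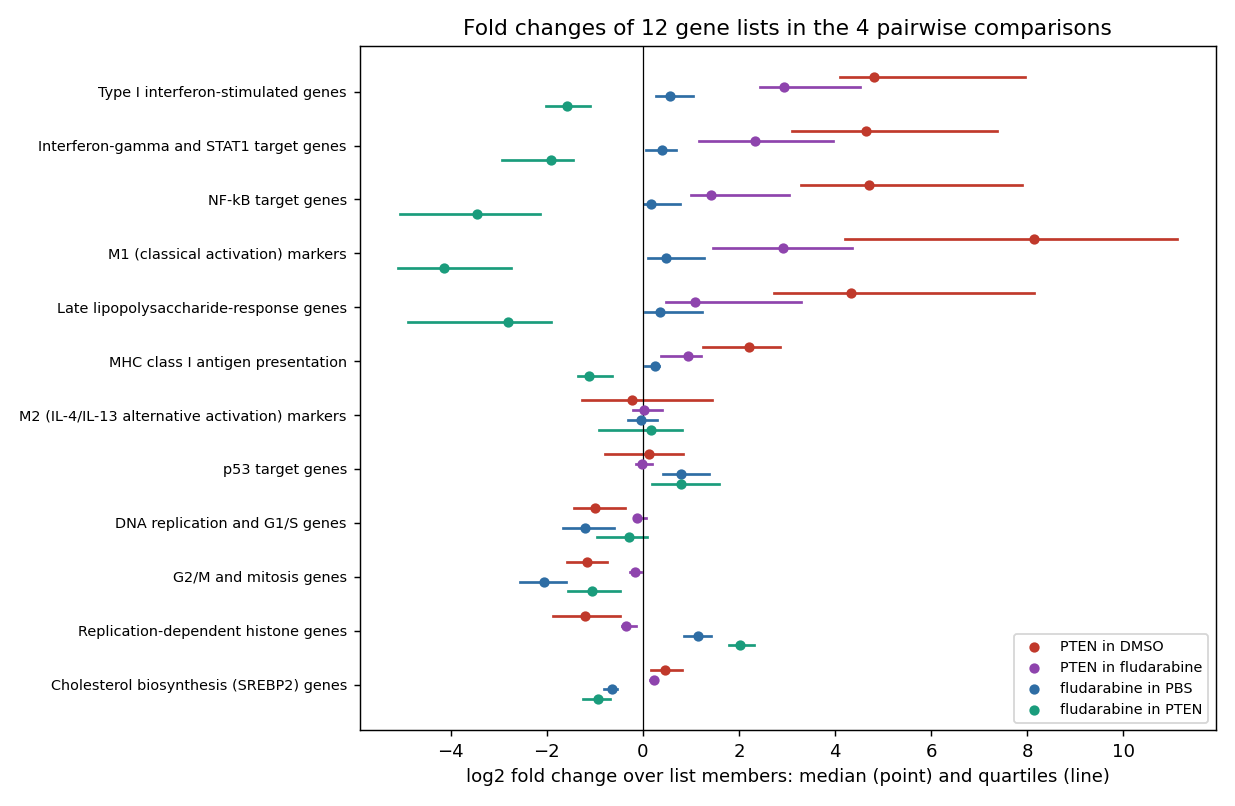
Median log2 fold change with quartiles of 12 gene lists in 4 comparisons. Inflammatory lists rose with PTEN and fell with fludarabine in PTEN-treated cells, and replication and mitosis lists fell with fludarabine in cells without PTEN; the replication list in PTEN-treated cells had a median of 0.05 under library size alone.

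Fludarabine without PTEN lowered replication, mitosis and sterol synthesis transcripts and raised p53 targets and histone transcripts. Interferon-stimulated genes were slightly higher (camera adjusted p = 2.18e-22), a call lost with an estimated correlation (adjusted p = 0.0862). The largest decreases were Uhrf1 (28.1 to 3.01 CPM, -3.21), Rrm2 (-3.13), Pclaf (-3.00), Kntc1 (-2.94), Cenpf (-2.93), Kif2c (-2.92), Pbk (-2.92), Aspm (-2.92), Ccna2 (-2.89), Ccnb2 (-2.81), Plk1 (-2.77) and Anln (-2.77). Mki67 fell from 134 to 26.5 CPM (-2.33, edgeR adjusted p = 6.69e-11). The largest increases were Thbs1 (12.8 to 130 CPM, 3.35), Inka2 (2.80), Phlda3 (2.48), Mx1 (5.73 to 29.1 CPM, 2.35), Mmp8 (2.10), Ak1 (3.56 to 14.2 CPM), Ms4a6b (1.89), Ifit1 (1.88), Mmp13 (1.85), Psrc1 (1.82), Cav1 (1.75) and Cdkn1a (166 to 549 CPM, 1.72, adjusted p = 4.13e-23). All 4 fludarabine libraries lay on one side of the 4 controls in each of these genes.

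All 40 mitosis genes were lower (median -2.05, camera adjusted p = 6.82e-107), as were 38 of 39 replication genes (-1.20, 1.99e-57), including Mcm5 (-2.13), Rrm1 (-1.48), Bub1 (-2.47) and Tacc3 (-1.48). The p53 targets were higher in 29 and lower in 1 of 33 (median 0.79, camera adjusted p = 6.93e-55), with Trp53inp1 (1.52), Ccng1 (1.37) and Mdm2 (1.19). All 13 histone genes were higher (median 1.15, camera adjusted p = 8.04e-08), with Hist1h3d (1.55), Hist1h2bg (1.24) and Hist1h2bc (0.87). All 24 cholesterol synthesis genes were lower (median -0.63, camera adjusted p = 1.15e-32), including Dhcr24 (-1.09), Cyp51 (-0.87) and Insig1 (-0.65). Fatty acid synthesis genes were lower in 13 and higher in 1 of 18 (-0.28, 1.75e-11), including Fads2 (-1.14), Scd1 (-1.12) and Fasn (-0.89). These 6 lists, neutrophil markers (3 of 6 higher; median 0.57, camera adjusted p = 0.000405) and phagocytic receptors (10 higher, 4 lower; median 0.06, camera adjusted p = 0.0109) kept an adjusted p of at most 0.038 with an estimated correlation. Mmp8 (2.10), Csf3r (0.77), Gas6 (0.65) and Colec12 (0.56) belonged to the last 2 lists.

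Interferon-stimulated genes were higher in 35 of 42 with fludarabine alone (median 0.57, camera adjusted p = 2.18e-22, adjusted p = 0.0862 with an estimated correlation), including Ifi44 (1.28), Oas3 (0.98), Ifi204 (0.62) and Slfn5 (0.62). Class II antigen-presentation genes were lower in 8 of 11 (median -0.45, camera adjusted p = 2.04e-06, adjusted p = 0.0862 with an estimated correlation), with Ciita (-0.90) and H2-DMb1 (-0.70). Interferon-gamma and STAT1 targets (17 higher, 1 lower of 35; median 0.41, camera adjusted p = 0.000115, adjusted p = 0.356 with an estimated correlation) and class I antigen presentation (11 higher, 1 lower of 23; 0.25, 0.000497, adjusted p = 0.301 with an estimated correlation) were higher in part, with Icam1 (0.87), Irgm1 (0.51) and H2-T22 (0.54). Late lipopolysaccharide-response genes (9 higher, 1 lower of 29; median 0.36, camera adjusted p = 0.000405, adjusted p = 0.301 with an estimated correlation) rose in few members, such as Slpi (1.85) and Clec4d (1.03). The same held for M1 markers (5 higher, 1 lower of 27; 0.48, 0.00282, adjusted p = 0.447 with an estimated correlation) and chemokines (7 higher, 2 lower of 24; 0.42, 0.0195, adjusted p = 0.333 with an estimated correlation), with Cd80 (1.30) and Cx3cl1 (1.64). NF-kB targets (5 higher, 3 lower; median 0.17, camera adjusted p = 0.052) and JAK-STAT components (10 higher, 1 lower; median 0.07, camera adjusted p = 0.0661) were not called. NF-kB targets passed without DMSO+PBS replicate 1 (0.0458), DMSO+PTEN replicate 4 (0.0461), Fludarabine+PBS replicate 3 (0.0412) or Fludarabine+PTEN replicate 1 (0.046) or 2 (0.0332), and JAK-STAT components without DMSO+PBS replicate 2 (0.045). Without the filter on low counts both passed (0.0296 and 0.0193).

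Smaller list changes did not hold with an estimated correlation. They were apoptosis regulators (14 higher, 5 lower; camera adjusted p = 0.00262, adjusted p = 0.234 with an estimated correlation), with Bbc3 (1.16) and Bax (0.68), and NRF2 targets (11 higher, 1 lower; 0.000887, adjusted p = 0.183 with an estimated correlation), with Cat (0.37). Another was stress-response genes (16 lower, 3 higher; 0.00697, adjusted p = 0.183 with an estimated correlation), with Phgdh (-1.89), Asns (-1.24) and Sesn2 (1.42). Macrophage identity markers (6 higher, 2 lower; camera adjusted p = 0.0241, adjusted p = 0.462 with an estimated correlation), oxidative phosphorylation (16 of 36 lower; 0.0286, adjusted p = 0.487 with an estimated correlation), and fibroblast markers (6 of 13 higher; 0.0299, adjusted p = 0.456 with an estimated correlation) were called narrowly. So were lysosome genes (14 higher, 5 lower; 0.0356, adjusted p = 0.525 with an estimated correlation) and immediate-early genes (8 higher, 3 lower; 0.0381, adjusted p = 0.333 with an estimated correlation). Itgam (0.49), Lyz2 (0.58), Acta2 (0.96), Ctsk (0.35) and Ier5 (0.52) were among their members. The oxidative phosphorylation call was lost without DMSO+PBS replicate 2 (0.0754) or 4 (0.0544), and the fibroblast call without DMSO+PBS replicate 2 (0.0653) or 3 (0.0789) or Fludarabine+PBS replicate 2 (0.0675). The lysosome call was lost without DMSO+PBS replicate 3 (0.0533) or Fludarabine+PBS replicate 2 (0.0584), and the immediate-early call without these (0.0533 and 0.0584) or Fludarabine+PBS replicate 1 (0.0517).

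Of the inflammatory genes, Stat1 (0.17, edgeR adjusted p = 0.0262), Jak2 (0.14, adjusted p = 0.0159), Irf1 (0.32, adjusted p = 0.00879), Gbp2 (0.45, adjusted p = 0.00416) and Cd86 (0.48, adjusted p = 0.0367) were slightly higher with fludarabine alone. The Stat1 call was lost without DMSO+PBS replicate 1 (0.0658) or 3 (0.0841) and without Fludarabine+PBS replicate 1 (0.0508) or 4 (0.1). That of Jak2 was lost without DMSO+PBS replicate 1 (0.0536) or Fludarabine+PBS replicate 2 (0.0631), and that of Cd86 without DMSO+PBS replicate 1 (0.0597), 2 (0.066) or 4 (0.127) or Fludarabine+PBS replicate 2 (0.0591) or 3 (0.23). Cxcl10 (2.35, adjusted p = 0.0831) and Nos2 (3.36, adjusted p = 0.0848, at 0.627 CPM) were not called, but DESeq2 called them (3.44e-07 and 2.44e-05). Cxcl10 passed in a fit of the compared groups (7.9e-06) and without Fludarabine+PTEN replicate 1 (0.0272) or 2 (0.0308), and Nos2 without DMSO+PTEN replicate 4 (0.0129) or Fludarabine+PTEN replicate 2 (0.04). Il6 (adjusted p = 0.475) and Il1b (adjusted p = 0.422) were called only by DESeq2 (0.00939 and 0.0065) or, for Il1b, in a fit of the compared groups (0.00311). Tnf (0.25, adjusted p = 0.408) passed only in the latter (0.0271). Il12b, with 2 counts in each group, and Cxcl9 (adjusted p = 0.887) were too low for a comparison.

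Arg1 (0.64, edgeR adjusted p = 0.000119) and Chil3 (0.51, adjusted p = 0.0244) rose, and Mrc1 (-0.31, adjusted p = 0.000258), Cd163 (-0.79), Plxdc2 (-0.30, adjusted p = 0.00469), Retnla (-0.33, adjusted p = 0.03), Il10 (-1.49, adjusted p = 0.000262) and Dck (-0.41, adjusted p = 7.71e-10) fell with fludarabine alone. Chil3 lost its call without DMSO+PBS replicate 1 (0.0549), 3 (0.0611) or 4 (0.0614) or Fludarabine+PBS replicate 2 (0.0784). Retnla lost its call without DMSO+PBS replicate 2 (0.0964) or 4 (0.0731) or Fludarabine+PBS replicate 1 (0.0791), 3 (0.0566) or 4 (0.0947). Pten did not change (0.08, adjusted p = 0.125), and passed without DMSO+PBS replicate 1 (0.04) and in a fit of the compared groups (0.0457). M2 markers went both ways (10 higher, 12 lower; median -0.03, camera adjusted p = 0.478).

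Fludarabine without PTEN changed 4766 genes, 2235 higher and 2531 lower, of which 410 changed at least 2-fold (176 higher, 234 lower). Camera called 23 of 35 lists, 8 of them with an estimated correlation as well. Adjusted over the list alone, the counts above were the same except for interferon-stimulated genes (38 higher, 1 lower), interferon-gamma and STAT1 targets (18 higher), class I (12 higher), M1 markers (4 higher) and NF-kB targets (4 higher). Other exceptions were p53 targets (30 higher), replication genes (39 lower), oxidative phosphorylation (18 lower), stress-response genes (17 lower), macrophage (7 higher) and fibroblast markers (7 higher). Under library size alone the median gene shifted by 0.01. Most changes were below 2-fold, and calls near the threshold depended on single libraries.

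In PTEN-treated cells, fludarabine lowered the inflammatory transcripts and left histone and p53-target transcripts higher. Stat1 was 139 CPM with fludarabine against 401 CPM without it (-1.53, SE 0.04, edgeR adjusted p = 6.64e-24), and Jak2 (-2.58), Irf1 (-1.88), Gbp2 (-3.19), Cxcl9 (-4.27), Cxcl10 (-4.14), Nos2 (-5.09), Tnf (-4.99), Il1b (-5.88) and Cd86 (-2.80) were lower in all 4 libraries. The largest decreases were Gfi1 (-7.82), Il12a (-7.45), Il6 (-7.02, adjusted p = 2.33e-12), Shisa3 (-6.96), Il12b (-6.48) and Ptx3 (-6.18). The largest increases were Cxcr4 (1.56 against 60.1 CPM, 5.26), Lpin1 (4.84), Inka2 (4.40), Cnr2 (4.23), Bmf (4.23) and Fam214a (4.14). Arg1 (1.63, adjusted p = 1.08e-08), Cd163 (1.82), Mrc1 (0.42), Pten (0.46) and Mdm2 (0.48) were higher, and Cdkn1a (-1.92), Mki67 (-2.59) and Dck (-0.77) lower. Plxdc2 (-0.36, adjusted p = 0.000567) and Retnla (-0.38, adjusted p = 0.00688) lost their calls under library size alone (0.857 and 0.762). Chil3 (0.30, adjusted p = 0.112) gained one there (0.00225), with replicate number as a block (0.000803) and without DMSO+PTEN replicate 2 (0.0149), and Il10 was not different (0.15, adjusted p = 0.578).

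All 42 interferon-stimulated genes (median -1.58, camera adjusted p = 3.29e-36), all 35 interferon-gamma and STAT1 targets (-1.91, 2.05e-32), and all 32 NF-kB targets (-3.45, 1.73e-43) were lower. So were 26 of 27 M1 markers (-4.14, 1.56e-24), 26 of 29 late lipopolysaccharide-response genes (-2.80, 4.96e-20) and 22 of 24 chemokines (-3.52, 7.18e-13). These 6 lists kept an adjusted p of at most 0.0269 with an estimated correlation. Ifi44 (-2.18), Icam1 (-3.52), Traf1 (-3.39), Cd38 (-3.91), Saa3 (-5.09), Ccl5 (-5.22) and Ccl17 (-4.65) were among them. Class I genes were lower in 22 of 23 (median -1.11, camera adjusted p = 1.09e-10, adjusted p = 0.0535 with an estimated correlation) and class II genes in 8 of 11 (-0.59, 0.0222, adjusted p = 0.409 with an estimated correlation). JAK-STAT components (19 lower, 6 higher; median -0.68, camera adjusted p = 3e-05, adjusted p = 0.0945 with an estimated correlation), apoptosis regulators (19 lower, 7 higher; -0.55, 2.19e-05, adjusted p = 0.0875 with an estimated correlation) and dendritic cell markers (5 lower, 1 higher; -0.88, 0.0122, adjusted p = 0.208 with an estimated correlation) were lower in part, with Tap2 (-1.72), H2-DMb1 (-1.27), Il13ra1 (-2.01), Casp7 (-2.08) and Fscn1 (-5.41). With library size alone, medians shrank for class II genes (-0.25; 7 lower, 3 higher), JAK-STAT components (-0.34; 16 lower, 11 higher), apoptosis regulators (-0.21; 17 lower, 11 higher) and dendritic cell markers (-0.54).

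The p53 targets were higher in 24 and lower in 6 of 33 (median 0.79, camera adjusted p = 0.000121, adjusted p = 0.0149 with an estimated correlation), with Trp53inp1 (3.62), Phlda3 (3.21) and Zmat3 (1.99). All 13 histone genes were higher (median 2.03, camera adjusted p = 0.00827, adjusted p = 0.0431 with an estimated correlation), including Hist1h3d (3.11) and Hist1h1c (2.03), though the call was lost under library size alone (adjusted p = 0.0625). Mitosis genes were lower in 35 and higher in 2 of 40 (median -1.06, camera adjusted p = 0.00464, adjusted p = 0.623 with an estimated correlation), with Tpx2 (-2.10) and Birc5 (-2.09) against Cenpa (1.12). Replication genes were lower in 20 and higher in 8 (median -0.29, camera adjusted p = 0.293; 14 higher, 16 lower and median 0.05 under library size alone, adjusted p = 0.0379 without the filter on low counts), with E2f8 at -2.43. Cholesterol synthesis genes were lower in 21 and higher in 1 of 24 (median -0.92, camera adjusted p = 1.01e-06, adjusted p = 0.232 with an estimated correlation), with Hsd17b7 (-1.64) and Hmgcr (-1.23), and a median of -0.58 under library size alone. PI3K-AKT-FOXO genes were higher in 20 and lower in 13 of 36 (median 0.30, camera adjusted p = 0.0408, adjusted p = 0.117 with an estimated correlation), with Foxo3 (2.31) and Inpp5d (1.56). The call was lost with RLE factors (0.0504), without the filter on low counts (0.0747), with replicate number as a block (0.0607) and without DMSO+PTEN replicate 1 (0.0542) or 3 (0.0543) or Fludarabine+PTEN replicate 2 (0.0566). It was kept with library size alone (23 higher, 8 lower; median 0.65, adjusted p = 0.00957). M2 markers (median 0.17, mean -0.18, camera direction up), phagocytic receptors (0.16, -0.28, up) and fatty acid synthesis genes (-0.42, 0.06, down) had medians and means of opposite sign. Their medians were 0.51, 0.50 and -0.08 under library size alone.

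Fludarabine changed 8947 genes in PTEN-treated cells, 4713 higher and 4234 lower, of which 2658 changed at least 2-fold (1470 higher, 1188 lower). Camera called 16 of 35 lists, 8 of them with an estimated correlation as well, and adjusted over the list alone the counts above were the same except for JAK-STAT components (20 lower). Across genes, the effects of fludarabine with and without PTEN correlated at r = 0.117, where genes are not independent replicates. Genes higher in both numbered 1332 (901.8 for independent sets), such as Inka2, Phlda3 and Mdm2, and genes lower in both 1361 (917.5), such as Mki67 and Dck. Under library size alone the median gene shifted by 0.34, with 7472 genes higher and 2325 lower. This comparison holds the effect of fludarabine itself together with its effect on the PTEN response.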

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

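The tests of explanations and the alternative groupings of libraries below were chosen only after the results had been seen. The response to PTEN was smaller with fludarabine, with a slope of 0.306 on the response without it. Suppose every induced gene had lost the same share of its response, as with mixed libraries. Interferon-stimulated genes and NF-kB targets would then have kept the same share of their CPM increase. They kept medians of 0.275 (42 genes) and 0.0593 (SE 0.00542, 32 genes). The difference of 0.215 (SE 0.00833) argues against such a uniform dilution. Whether cells not responding to PTEN itself raised interferon-stimulated genes through signals from other cells was not tested, so fewer responding cells remain possible. TMM factors are unlikely to account for the smaller response, because the slope with library size only was 0.289. A lower effective amount of PTEN in the fludarabine cultures could give the same pattern, and with 1 dose this cannot be told apart from an action of fludarabine downstream of PTEN.

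Interferon-stimulated genes were slightly higher with fludarabine alone, with a median of 0.57 and an adjusted p = 0.0862 with an estimated correlation, at which camera did not call the list. Carry-over of reads from DMSO+PTEN libraries alone would have raised NF-kB targets by the same share of their PTEN response. The excess was larger for interferon-stimulated genes by 0.00769 (SE 0.00117). Carry-over from Fludarabine+PTEN libraries would itself favour interferon-stimulated genes, since these kept 0.275 of their response there and NF-kB targets 0.0593. The comparison therefore cannot decide on carry-over. A loss of cycling cells that raised all other macrophage transcripts alike would not have separated these lists. The lower quartile of interferon-stimulated genes (0.28) lay above the upper quartile of macrophage identity markers (0.19), which argues against such a uniform rise. Whether cycling cells held fewer interferon-stimulated transcripts was not tested, so their loss remains possible. No other cause was tested.

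Late lipopolysaccharide-response genes were higher with PTEN in 28 of 29. Endotoxin carried with the PTEN preparation could produce this, as could PTEN itself, and no group received a control preparation that would tell them apart. The same limit holds for every other comparison with PTEN and for the interaction. It includes the interferon, STAT1, NF-kB, M1 and chemokine lists.

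Among ways to divide the 8 compared libraries into groups of 4, only 1 of 35 gave as many changed genes as the treatment in each simple comparison. That was the treatment itself, for PTEN without fludarabine (9027 genes, 0 in the next), PTEN with fludarabine (4132, 0), fludarabine without PTEN (5080, 0) and fludarabine with PTEN (8676, 0). Every other division mixed treated and control libraries in both groups, which with groups this far apart leaves little room for calls. These counts therefore do not bear on a batch or on shared cultures. For the interaction, residuals of a model without it were exchanged between libraries and tested with limma instead of edgeR. Only 1 of 100 draws, the real one, reached 7681 genes, and the next highest reached 6109. The exchanged residuals hold the interaction itself, so no conclusion is drawn from these draws.

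Single libraries stood apart from the other 3 of their group by Dixon's ratio in 10 of 100 gene groups tested, with 5 expected, and in 20 of 276 groups of other named genes, with 13.8 expected. The expected numbers take the gene groups as independent, which correlated genes of one library are not. Ratios were 1 for Il6 in DMSO+PBS replicate 4, from 1 count, and 1 for Il12b in the same library, from 2 counts. For Nos2 they were 0.985 in DMSO+PTEN replicate 4 and 0.904 in Fludarabine+PTEN replicate 2, and for Il1b 0.910 in the latter. For Tnf they were 0.868 in DMSO+PBS replicate 4 and 0.890 in Fludarabine+PBS replicate 3. For Mki67 they were 0.894 in DMSO+PTEN replicate 4 and 0.912 in Fludarabine+PBS replicate 2, and for Dck 0.913 in DMSO+PTEN replicate 2. Fludarabine+PTEN replicate 2 also had the highest CPM of its group for Jak2, Irf1, Cxcl9, Cxcl10, Gbp2, Tnf, Il6, Il12b and Cd86, but not for Stat1. Its Il6 value was 7.47 CPM, against 3.50 to 4.44 CPM in the other Fludarabine+PTEN libraries.

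The PTEN effect differed between cells with and without fludarabine in lists with a median interaction of -4.97 (M1 markers), -1.97 (interferon-stimulated genes), -2.32 (interferon-gamma and STAT1 targets), -0.70 (JAK-STAT components), -1.25 (class I antigen presentation), -3.35 (NF-kB targets), -2.85 (late lipopolysaccharide-response genes) and -3.50 (chemokines). Further medians were 0.81 (replication), 1.01 (mitosis), -0.71 (apoptosis regulators), -0.33 (NRF2 targets) and -1.08 (dendritic cell markers). With an estimated correlation 7 of these calls were lost, those of M1 markers (adjusted p = 0.0505), JAK-STAT components (0.078), replication (0.208), mitosis (0.584), apoptosis regulators (0.05), NRF2 targets (0.307) and dendritic cell markers (0.238). Among genes named whatever their result it differed for Stat1 (-1.70), Pten (0.37), Jak2 (-2.73), Irf1 (-2.20), Cxcl10 (-6.49), Gbp2 (-3.64), Nos2 (-8.44, fitted from 1 count in each DMSO+PBS library), Tnf (-5.23), Il6 (-10.13, fitted from 1 count in DMSO+PBS), Il1b (-7.31), Cd86 (-3.27), Arg1 (0.99), Mrc1 (0.72), Cd163 (2.61), Il10 (1.64), Cdkn1a (-3.64), Mdm2 (-0.71) and Dck (-0.36), and for 67 of 69 other named genes.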

How the results depend on the processing

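Shares on the log2 scale and shares without Fludarabine+PTEN replicate 2 were added only after the results had been seen. The number of genes changed by PTEN without fludarabine was 9245, and 9260 with RLE factors, 10260 with library size only, 9624 without the filter, 9139 in DESeq2, 9027 with the compared groups only, 3350 at 2-fold or more, and 9041 to 9310 with one library left out. For PTEN with fludarabine these were 4076, 4152, 5486, 3945, 3892, 4132, 489 and 3661 to 4179. For the interaction they were 7671, 7650, 9074, 7662, 7483, none for the compared groups only, 2475 and 7463 to 7614. For fludarabine without PTEN they were 4766, 4783, 4792, 4623, 4500, 5080, 410 and 4252 to 4884, and for fludarabine with PTEN 8947, 8959, 9797, 9239, 8811, 8676, 2658 and 8686 to 8981. The slope of 0.306 was 0.289 with library size only, 0.294 without the filter and 0.291 to 0.310 with one library left out. With replicate number as a block, the counts were 9327, 4406, 7791, 5105 and 9043 and the slope 0.306. Of 16 libraries, 14 matched best with a library of their own number, which points to some link between libraries of one number. Residual correlations of same-number pairs were low, above 0.1 in 11 of 24 (range -0.0143 to 0.281). The labels do not state a pairing and the main fit did not model one, but it cannot be excluded. With library size only, some genes near 0 shifted with the whole gene set and gained a call. Plxdc2 (0.03 to -0.41) and Chil3 (0.00 to -0.43) did so with PTEN alone, and Plxdc2 in the interaction (-0.06 to 0.27). The difference in retained share of 0.215 was 0.310 and 0.364 on the log2 scale with prior counts of 2 and 20, 0.278 with library size only and 0.213 without Fludarabine+PTEN replicate 2. Of 175 list results, 38 were weaker with an estimated correlation.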

Other observations

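Histone transcripts captured through poly(A) rose with fludarabine in 13 of 13 genes, both without PTEN (median 1.15) and with it (2.03), while mitosis transcripts fell in 40 of 40 and 35 of 40. In PTEN-treated cells, the histone call was lost with library size only (adjusted p = 0.0625) and the mitosis call with an estimated correlation (adjusted p = 0.623). With PTEN alone 10 of 13 histone genes fell. The copies are near-identical, so single histone genes cannot be separated with certainty.

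Cholesterol synthesis genes fell with fludarabine in 24 of 24 without PTEN and in 21 of 24 with it, the latter with adjusted p = 0.232 with an estimated correlation, and fatty acid synthesis genes fell in 13 of 18 without PTEN.

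Mki67 (0.98) and Tpx2 (1.59) rose with PTEN while 37 of 40 mitosis genes fell.

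Il10 was 1.23 CPM without treatment, 1.59 CPM with PTEN, 0.439 CPM with fludarabine and 1.79 CPM with both.

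Reads of the ligands Ifnb1, Ifng, Il4 and Il13 were few. Summed over the 4 libraries of DMSO+PBS, DMSO+PTEN, Fludarabine+PBS and Fludarabine+PTEN, Ifnb1 had 0, 216, 1 and 34 counts, Ifng 0, 1, 0 and 0, Il4 132, 35, 305 and 168, and Il13 0, 1, 1 and 1.

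Induced genes were those past the threshold and at least 2-fold higher with PTEN without fludarabine. The median retained share of the PTEN response over 1129 induced genes with a mean of at least 5 CPM was 0.159 (quartiles 0.0899 and 0.252). List shares covered induced members only, without a CPM minimum. They were 0.0303 for M1 markers (25 genes), 0.0435 for chemokines (22) and 0.0512 for late lipopolysaccharide-response genes (27). For interferon-gamma and STAT1 targets the share was 0.184 (33 genes) and for class I antigen presentation 0.251 (19 genes).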
